A study of Mus musculus with 11 samples.

How the data were processed

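RNA-seq values were analysed for the 3 libraries labelled TKO, TKO_FL and TKO_602, and samples were grouped by the genotype in their titles. The submitters' processing notes name Trim Galore, HISAT2, SAMtools, Subread and featureCounts and the mm10 genome, with no order. Per the file headers, the gene count table was made with featureCounts version 2.0.6 in its paired mode, on the RefSeq gene annotation of mm10, with no strand option, no option to count read pairs and no option for reads that map to several places. Counts are therefore of reads, each mate counted alone. Without strand, reads of a gene and its antisense partner cannot be told apart, and reads that fall on 2 overlapping genes, or that map equally well to copies, are left out by the default settings. The library kit as described in the labels does not mark strand.

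The authors also deposited a gene table and a repeat table, named TPM, that hold values used here for TKO and TKO_FL. The columns of the deposited gene signal table summed to 10000000, 10 times the total that defines TPM, so the deposited values were divided by 10 and called TPM. Multiplying by the exonic length gave whole numbers of fragments for 100% of values (tolerance 1e-06 of a fragment), 10860312 in TKO and 10084490 in TKO_FL, and the count table held a median of 1.95 reads per fragment in both. The deposited repeat signal columns summed to 9802099 for TKO and 9804588 for TKO_FL and were divided by 10 likewise. Each of the 442429 repeat features joins same-numbered copies of a repeat name across chromosomes, and 15.0% of those with signal in TKO held fractions of a fragment, so fragments that map to several places had been shared out. The repeat annotation and the counting command are not given in the sources used here. The features add up to 1327700 fragments in TKO and 1179815 in TKO_FL. Each table has 11 columns of libraries that match none of these samples, and they were not used.

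The plan fixed before the data were examined assumed TPM for all 3 libraries. TKO_FL was compared with TKO on TPM. Because TKO_602 has counts only, its comparisons used CPM with TMM factors (0.980 for TKO, 0.983 for TKO_FL and 1.04 for TKO_602), computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The factors differed by 0 at 5 decimals from those of edgeR 4.0.16 in R 4.3.3. Log2 folds are log2 of the ratio of values plus a pseudocount of 1, over genes with a value of at least 1 in one of the libraries, with a threshold of 2-fold. There was 1 library per genotype, so no test across libraries was run. Exact 95% binomial intervals were computed from fragments (TKO_FL against TKO) or from reads divided by 2 (the others), and a value of 0 was bounded by a floor of 3 fragments, or 6 reads. PCR duplicates are not removed by these intervals, which cover counting error only.

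Gene lists were fixed before the data were examined. They cover DNA methylation and demethylation machinery, germline genes, 2-cell-stage genes, naive pluripotency, formative and primed pluripotency, maternally and paternally expressed imprinted genes, the Rhox, Mage and Xlr clusters, trophoblast, primitive endoderm, mesoderm, neuroectoderm, fibroblast feeder markers, the interferon and double-stranded RNA response, p53 targets, cell cycle, glycolysis and hypoxia, mitochondrially encoded genes, ribosomal proteins, replication-dependent histones, silencing factors, stress and immediate early genes, Hox genes and reference genes. The mitochondrial and histone lists had 0 members in the gene table. A list's median was placed among 10000 random lists of its size matched on mean expression in 20 bins. Because members of a list are often regulated together, that percentile describes these libraries and is no p-value. Named genes are all measured DNA methylation genes, the 10 highest and 10 lowest folds per comparison among genes with a value of at least 5 (predicted and accession-like symbols left out), up to 4 members per list with the largest folds, and for repeats the 5 highest and 5 lowest names and those needed to describe a list. The text gives a selection of these, some that meet the rule are not reported here, and it names any other gene as chosen after its values were seen. Repeat values were summed per repeat name, with a minimum sum of 5 TPM.

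The fold and list steps were tested on simulated counts with known changes. Both libraries of a pair were drawn from the proportions of a single library with counting error only. The shares below therefore leave out variation between cultures, batches or alignments and are no error rates for the real comparisons. For TKO_FL against TKO, over 13214 simulated genes, 38.5% of 2-fold, 95.5% of 4-fold and 100% of 8-fold changes were called, and 112 of 13018 unchanged genes passed the threshold. For TKO_602 against TKO, over 13225 genes, the shares were 35.4%, 97.0% and 98.5%, with 0 of 13028 unchanged genes called. For TKO_602 against TKO_FL, over 13356 genes, they were 34.3%, 92.5% and 100%, with 0 of 13157. Alternatives varied the pseudocount, the filter, the scaling, the genes included and the threshold.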

Results

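The series profiled mouse embryonic stem cells of the J1 line that carry mutations of DNA methyltransferases, the enzymes that place methyl groups on cytosine. It holds 11 samples. Poly(A)-selected RNA was sequenced from 3 of them at day 0, 1 library for each of the genotypes labelled TKO, TKO_FL and TKO_602. The labels of other samples spell the first genotype as DNMT TKO, and what FL and 602 stand for is not given in the sources used here. The other 8 samples are immunoprecipitations of methylated or hydroxymethylated DNA from cells labelled TKO and DKO at days 0 and 7, which were not analysed here; the series' design text names TKO_FL instead of TKO for them. The cells grew on mouse embryonic fibroblast feeders with serum and LIF. The gene counts summed to 21133660 reads for TKO, 19573689 for TKO_FL and 43158441 for TKO_602. With 1 library per genotype, every difference below lies between 2 libraries, has no replicate check and carries no p-value. The intervals given are 95% exact binomial intervals of the ratio of counts, computed without a pseudocount, and they cover counting error only.

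The genes of the DNA methylation machinery were read first, since they bear on the labels. Dnmt1, the maintenance methyltransferase (mm10 chromosome 9, 20907206 to 20959888, minus strand), had 54.9 TPM in the TKO library and 1177 TPM in the TKO_FL library, a log2 fold of 4.40 (interval 4.35 to 4.49). As CPM, read counts scaled by library size, Dnmt1 stood at 159 in TKO, 3364 in TKO_FL and 2444 in TKO_602. The TKO_602 library thus had a log2 fold of 3.93 against TKO (interval 3.87 to 4.01) and of -0.46 against TKO_FL. Dnmt3b, a de novo methyltransferase, had 71.7 CPM in TKO, 34.0 in TKO_FL and 11.9 in TKO_602. Dnmt3l, its catalytically inactive cofactor, followed with 658, 408 and 226 CPM. Dnmt3a had 35.2, 36.1 and 27.8 CPM. A gene total adds reads from all annotated exons, so reads of Dnmt3a and Dnmt3b in the TKO library do not show whether a deleted part is present, and reads of an introduced Dnmt1 cDNA cannot be separated from those of the endogenous gene. Reads from any fibroblast feeder cells in a library cannot be told apart from those of the stem cells either. Uhrf1, which brings DNMT1 to replicated DNA, had 581, 504 and 456 CPM. The dioxygenase genes had 716, 565 and 622 CPM for Tet1, 112, 101 and 89.5 for Tet2, and 23.1, 18.5 and 21.4 for Tet3. Uhrf2 had 62.9, 62.1 and 99.1 CPM. Among methyl-CpG-binding genes, Mbd1 had log2 folds against TKO of 0.06 in TKO_FL and 0.18 in TKO_602, Mbd2 of -0.12 and 0.18, Mbd3 of -0.18 and -0.60, and Mbd4 of -0.38 and 0.15. The median of the 14 measured members was -0.16 in TKO_FL against TKO (percentile 8.17 of 10000 random lists matched on expression), -0.15 in TKO_602 against TKO (percentile 26.3) and -0.01 in TKO_602 against TKO_FL (percentile 54.0).

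The comparison of TKO_FL with TKO set the library with high Dnmt1 against the one with low Dnmt1. Primitive endoderm genes made up the most shifted list: 15 of its 16 measured members were at least 2-fold lower in TKO_FL, none was higher, and the median log2 fold was -2.13, below every one of the 10000 matched random lists (percentile 0). Gata6, a transcription factor that specifies this lineage, had 15.3 TPM in TKO and 1.11 in TKO_FL (log2 -2.95, interval -4.62 to -3.06). Cubn, an endocytic receptor of visceral endoderm, had 31.4 and 2.56 TPM (log2 -3.19), and its partner Amn had 21.0 and 2.34 TPM (log2 -2.72). The basement membrane collagen gene Col4a1 had 199 and 28.3 TPM (log2 -2.77). Fibroblast feeder markers were lower too, with a median of -0.64 (percentile 0), and 5 of 25 members were at least 2-fold lower, among them Acta2 (49.1 and 15.5 TPM), S100a4 (111 and 46.6 TPM), Tagln (70.2 and 31.5 TPM) and Col5a2 (16.6 and 7.53 TPM). Other genes among the lowest folds were Srgn, a proteoglycan gene (69.3 and 4.50 TPM, log2 -3.68), Cyp26a1, which degrades retinoic acid (9.35 and 0.248 TPM, log2 -3.05), and Nostrin (11.9 and 0.612 TPM, log2 -3.01).

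Germline genes leaned the other way in TKO_FL. Of 41 measured members, 8 were at least 2-fold higher, none was lower, 32 lay above 0 and the median was 0.43 (percentile 100). Sycp3, a component of the synaptonemal complex, had 4.58 TPM in TKO and 21.3 in TKO_FL (log2 2.00). Stra8, which is needed for entry into meiosis, had 7.42 and 27.4 TPM (log2 1.76), Sohlh2 14.6 and 41.1 TPM (log2 1.43) and Tex14 was at a log2 fold of 1.32. Naive pluripotency genes had a median of 0.15 (percentile 99.95), with Jam2 at 43.3 and 100 TPM and Nr5a2 at 46.5 and 93.7 TPM, while 28 of the 29 members stayed within 2-fold. The medians of p53 targets (0.42, percentile 100), of glycolysis and hypoxia genes (0.22, percentile 99.96) and of ribosomal protein genes (0.09, percentile 99.8) were high in their matched lists although no member of any of them was 2-fold apart. Trp53inp1 was at 78.2 and 146 TPM, Cdkn1a at 82.6 and 135 TPM, and Bnip3 at 164 and 250 TPM. Of the p53 targets 12 of 17 lay above 0, and of the glycolysis and hypoxia genes 15 of 21. Members that went down included Perp (log2 -0.79), Ankrd37 (log2 -0.97) and Hk2 (log2 -0.54). Trophoblast genes went both ways, with 3 of 15 members at least 2-fold higher, 1 lower and a median of -0.31 (percentile 1.44): Tfap2c had 19.6 and 96.4 TPM (log2 2.24) and Esx1 1.28 and 6.78 TPM (log2 1.77), whereas the keratin gene Krt8 had 54.7 and 18.8 TPM (log2 -1.49). Paternally expressed imprinted genes had a median of -0.29 (percentile 0.38), and of 21 members none was at least 2-fold lower and 1 was higher, with Sgce against that direction at a log2 fold of 1.43. Hox genes (median -0.61, percentile 0.78) and mesoderm genes (median -0.65, percentile 2.04) had few measured members, 11 and 5, of which 1 and 0 were at least 2-fold lower. The medians of 3 of these lists came to lie within the central 95% of random lists under some settings: trophoblast with a TPM of at least 5 (-0.10, percentile 25.0), a pseudocount of 5 (-0.16, percentile 4.18) or no filter (percentile 3.90), paternally expressed imprinted genes with no filter (-0.09, percentile 8.25), and mesoderm with pseudocounts of 0.1 and 5, no filter or CPM (percentiles 3.90 to 5.97).

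The remaining lists of this comparison lay within the central 95% of random lists. Their medians were 0.02 for 2-cell-stage genes, -0.13 for formative and primed pluripotency, 0.13 for maternally expressed imprinted genes, 0.24 for the Rhox, Mage and Xlr clusters, 0.14 for neuroectoderm, -0.30 for the interferon and double-stranded RNA response, -0.06 for the cell cycle, -0.08 for retroelement and heterochromatin silencing factors, 0.09 for stress and immediate early genes and -0.09 for reference genes. Single members still moved apart, such as the signalling inhibitor gene Lefty1 (179 and 506 TPM), Dux (1.22 and 3.61 TPM), Slc22a18 (1.17 and 5.17 TPM), Fos (77.5 and 163 TPM) and Fosb (25.5 and 58.7 TPM). Over all 13642 genes with a TPM of at least 1 in one library, 489 were at least 2-fold higher in TKO_FL and 417 lower on the log2(TPM + 1) scale, which understates the folds of low genes. Of these 906 genes, 137 were shorter than 200 bases, 132 of them microRNA and small nuclear or nucleolar RNA genes by their symbols, and 9 of the 10 highest folds under the naming rule were of such short genes, resting on few fragments. Among genes of 200 bases or longer, a cut chosen after the values were seen, the highest after Dnmt1 were Lrrc31 (log2 2.66), the meiotic gene Meiob (2.36), Tfap2c (2.24), Ndufa4l2 (2.04) and Copz2 (2.00). The total depended on the pseudocount: it was 1621 with 0.1 and 189 with 5.

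**Figure D1:**
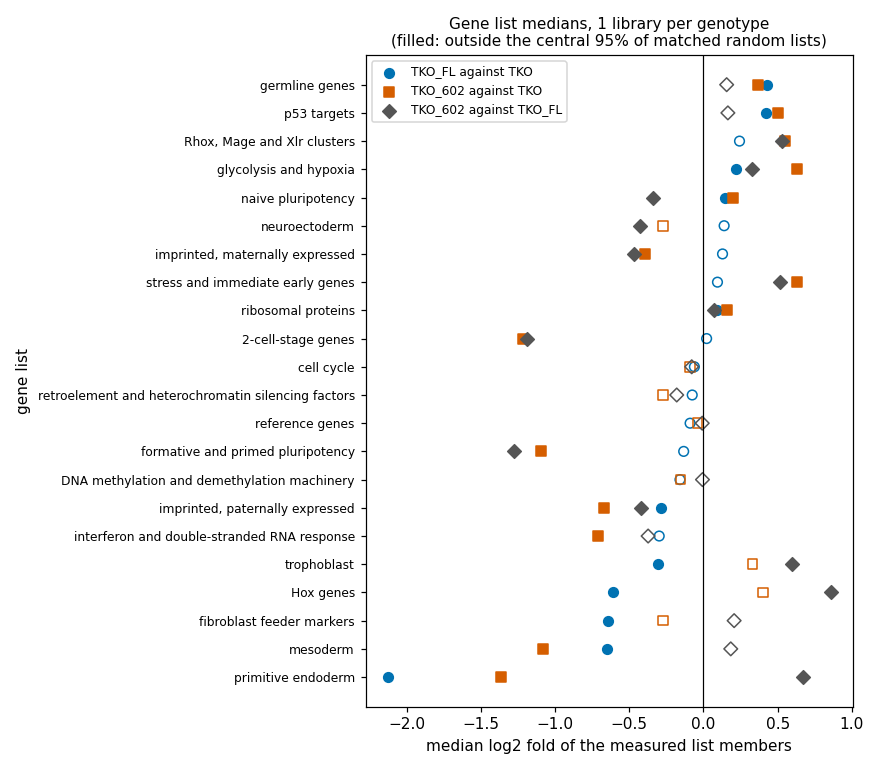
Median log2 fold (x axis) of the measured members of each gene list (y axis) in the 3 comparisons of single libraries, drawn as circles, squares and diamonds; filled symbols lie outside the central 95% of 10000 random lists matched on expression. Primitive endoderm genes have the lowest median of TKO_FL against TKO, -2.13, and also lie low in TKO_602 against TKO, at -1.37. TKO_FL against TKO is on TPM and the other comparisons are on CPM with TMM factors, so the sizes of their medians are not directly comparable.

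The comparison of TKO_602 with TKO was made on CPM with TMM factors, since the TPM table holds no TKO_602 values used here. Formative and primed pluripotency genes were lower: 10 of 18 members were at least 2-fold lower, none higher, and the median was -1.09 (percentile 0). Lef1, a transcription factor of Wnt signalling, had 50.9 CPM in TKO and 6.07 in TKO_602 (log2 -2.88, interval of the ratio -3.35 to -2.80), Foxd3 had 64.9 and 11.6 CPM (log2 -2.39), Otx2 had 50.1 and 14.2 CPM (log2 -1.75) and Cdh2 had 24.3 and 3.30 CPM (log2 -2.56). Of 16 measured 2-cell-stage genes, 9 were at least 2-fold lower (median -1.21, percentile 0), among them Tmem92 (4.44 and 0.379 CPM) and Zscan4a (2.75 and 0.134 CPM). Members of this list have near-identical copies, as may members of the Rhox, Mage and Xlr clusters, so the reads of both lists are uncertain. Primitive endoderm genes were again lower, 11 of 16 (median -1.37, percentile 0), with Cubn at 165 and 23.8 CPM, Dab2 at 97.8 and 14.5 CPM and Sox7 at 8.35 and 0.647 CPM. Fibroblast feeder markers had a median of -0.27 (percentile 3.00) and went both ways, with S100a4 at 25.5 and 2.63 CPM and Mmp2 at a log2 fold of 1.83. Both classes of imprinted genes had medians below 0. The paternally expressed ones had a median of -0.67 (percentile 0.02), 8 of 23 at least 2-fold lower and 2 higher, with Peg10 at 694 and 114 CPM and Mest at 207 and 48.4 CPM. The maternally expressed ones had a median of -0.39 (percentile 2.44), but 13 of 16 stayed within 2-fold, with Rian at 425 and 160 CPM, Mirg at 22.6 and 4.31 CPM and Slc22a18 the other way at a log2 fold of 1.73.

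Higher lists in TKO_602 included glycolysis and hypoxia genes (median 0.63, percentile 100), 5 of 21 at least 2-fold higher. Gapdh, a glycolytic enzyme gene that is often used as a reference, had 11.3 CPM in TKO, 15.4 in TKO_FL and 170 in TKO_602. It has a named pseudogene copy, and reads that map equally well to copies were left out. Its values and folds in every comparison are therefore uncertain. Vegfa had 29.1 CPM in TKO and 85.8 in TKO_602, and Car9 0.772 and 8.66. Stress and immediate early genes had a median of 0.63 (percentile 99.96), 5 of 19 at least 2-fold higher and 1 lower, with Fos at 76.1 and 364 CPM, Egr1 at 145 and 438 CPM and Gdf15 at 2.22 and 22.1 CPM. Germline genes had a median of 0.37 (percentile 98.1): 12 of 43 were at least 2-fold higher and 2 lower, led by Sycp3 (2.03 and 15.4 CPM), Stra8 (4.97 and 30.9 CPM), Sohlh2 (16.0 and 86.7 CPM) and Dpep3 (2.61 and 16.3 CPM). The medians were 0.51 for p53 targets (percentile 99.9), 0.55 for the Rhox, Mage and Xlr clusters (percentile 97.6), 0.20 for naive pluripotency (percentile 99.4) and 0.16 for ribosomal proteins (percentile 99.6), with 2 of 17, 8 of 26, 5 of 29 and 0 of 29 members at least 2-fold higher. Naive genes went both ways, 4 of them at least 2-fold lower, with Nr0b1 at 157 and 52.0 CPM, Lin28a at 503 and 200 CPM and Tcl1 at 39.3 and 110 CPM. The interferon and double-stranded RNA response (median -0.71, percentile 0.22) had 3 of 14 members at least 2-fold lower and none higher, and mesoderm genes (median -1.08, percentile 0.03) had 5 of 8 lower and 1 higher, with Ddx58, an RNA sensor, at 55.1 and 13.5 CPM and Kdr at 7.48 and 0.982 CPM. Some of these calls were lost under other settings: the interferon response (percentile 3.69) and maternally expressed imprinted genes (percentile 3.43) with a CPM of at least 5, the latter also without predicted symbols (percentile 2.83), mesoderm with no filter (median 0), germline genes with a pseudocount of 5 (percentile 97.1), and the Rhox, Mage and Xlr clusters with pseudocounts of 0.1 and 5, with no filter and without predicted symbols (percentiles 87.8 to 97.4). Within the central 95% lay trophoblast (0.33), neuroectoderm (-0.27), the cell cycle (-0.09), silencing factors (-0.27), Hox genes (0.40) and reference genes (-0.04). Members of these lists still differed, such as Tubb3 (91.6 and 14.6 CPM), Ccnd1 (150 and 35.6 CPM), Zfp57 (247 and 77.7 CPM), Krt7 (log2 2.64), Actb (3538 and 1587 CPM) and Ppia (2571 and 1232 CPM).

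Over 13748 genes with a CPM of at least 1 in one library, 1506 were at least 2-fold higher in TKO_602 than in TKO and 1108 lower. Among the highest folds were those of Hrc, a calcium-binding protein gene (1.21 and 65.0 CPM, log2 4.90), Dnmt1, Gapdh (log2 3.79) and Igfbp4 (14.3 and 204 CPM, log2 3.74). Among the lowest were those of Enox1 (131 and 4.40 CPM, log2 -4.62), Il1rl1 (26.8 and 0.870 CPM, log2 -3.90), Soga3 (35.4 and 1.67 CPM, log2 -3.77) and the proto-oncogene Myc (48.7 and 3.50 CPM, log2 -3.46). With a pseudocount of 5 the total of 2614 was 1212. Per the file headers the TKO_602 alignment came from another folder than the other 2, and its library was the deepest, so genotype and library batch cannot be told apart in this comparison or the next.

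Between TKO_602 and TKO_FL, the 2 libraries with high Dnmt1, 924 genes were at least 2-fold higher in TKO_602 and 667 lower among 13683. Formative and primed pluripotency genes (median -1.28, 10 of 18 lower, 1 higher) and 2-cell-stage genes (median -1.19, or -1.20 with the member at 0 placed at its bound, 11 of 15 lower) were below every matched random list. Lef1 had 42.4 CPM in TKO_FL and 6.07 in TKO_602, and Zic2 131 and 41.2. Primitive endoderm genes were higher in TKO_602 (median 0.67, percentile 99.95, 5 of 15 higher and none lower), with Gata6 at 1.56 and 10.0 CPM and Col4a1 at 86.7 and 224 CPM. Hox genes (median 0.86, percentile 99.8), trophoblast (0.60, percentile 99.5), the Rhox, Mage and Xlr clusters (0.53, percentile 99.4), stress and immediate early genes (0.52, percentile 99.9), glycolysis and hypoxia (0.33, percentile 99.98) and ribosomal proteins (0.07, percentile 99.2) were also high in their matched lists. Maternally expressed imprinted genes (-0.47, percentile 0.53), paternally expressed ones (-0.42, percentile 0.20), neuroectoderm (-0.43, percentile 1.95) and naive pluripotency (-0.34, percentile 0.89) were low, with 3 of 15, 5 of 23, 3 of 8 and 4 of 29 members at least 2-fold lower. The other way, 1 of the paternally expressed genes and 2 of the naive genes were at least 2-fold higher. Calls were lost for maternally expressed imprinted genes and for the Rhox, Mage and Xlr clusters with a pseudocount of 5 (percentiles 6.39 and 97.4) or no filter (3.62 and 96.1), and for neuroectoderm with a pseudocount of 5 (13.9); its median turned above 0 with no filter (0.10) and with a CPM of at least 5 (0.076). Within the central 95% lay germline genes (0.16), p53 targets (0.16), mesoderm (0.18), fibroblast feeder markers (0.21), the interferon response (-0.37), silencing factors (-0.18), the cell cycle (-0.08) and reference genes (-0.01). The lowest folds were those of Enox1 (95.4 and 4.40 CPM, log2 -4.16), Trh, the thyrotropin-releasing hormone gene (861 and 55.1 CPM, log2 -3.94), Msc (11.2 and 0.379 CPM, log2 -3.14) and Myc (35.5 and 3.50 CPM, log2 -3.02). Gbp3 had 110 reads in TKO_FL and 0 in TKO_602, with an upper interval limit of -5.07 in log2. The highest were Gapdh (log2 3.38), Micall2 (5.72 and 64.9 CPM, log2 3.29), Ppp1r3b (1.56 and 22.6 CPM, log2 3.20) and Hrc (log2 3.13). With a pseudocount of 5 the total of 1591 was 618.

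The differences of TKO_FL and TKO_602 from TKO were then set side by side over 13948 genes, both on the CPM scale. Of 440 genes at least 2-fold higher in TKO_FL and 1506 in TKO_602, 296 were higher in both, and of 339 and 1108 lower genes, 190 were lower in both. Independent lists would share 47.5 and 26.9, but the 2 lists are not independent, since both are set against the same TKO library. In opposite directions went 6 genes that were higher in TKO_FL and lower in TKO_602, and 1 gene that was the reverse. The correlation across genes, which are not independent replicates, was 0.60 (Pearson) and 0.56 (Spearman). Libraries were also simulated with counting error alone, all of them around the mean of the libraries, so without any real difference. The Pearson correlation was then 0.58, which the shared TKO library gives by itself. Because real differences are absent there, 0.58 is no benchmark for 0.60, and the correlation alone was not read as a shared difference. The same simulation gave shared means of 0.09 higher and 0.01 lower genes. The covariance was 0.24 against 0.016 in the simulation. Only 1 TKO library exists, so it could not be split, and part of the excess may come from that shared library.

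Repeat transcripts were compared between TKO_FL and TKO, the libraries with values in the repeat table. IAP elements, a family of endogenous retroviruses, were lower in TKO_FL, with a summed 2447 TPM in TKO and 578 in TKO_FL (log2 -2.08). The internal sequence IAPEz-int accounted for most of this, with 49880 fragments in TKO and 7370 in TKO_FL and 1891 and 317 TPM (log2 -2.57). Its long terminal repeats IAPLTR1_Mm (238 and 70.2 TPM) and IAPLTR1a_Mm (44.7 and 11.7 TPM) were lower as well, and so was IAPA_MM-int (40.7 and 5.27 TPM). Other IAP names moved less, such as IAPLTR2a2_Mm (24.9 and 22.3 TPM) and IAP1-MM_I-int (26.4 and 25.6 TPM), and of the 15 IAP names compared 5 were at least 2-fold lower. The related ETn and MusD elements were slightly higher, at 3154 and 3650 TPM (log2 0.21). Summed log2 folds were -0.08 for MERVL, -0.38 for MMERVK10C, -0.39 for VL30, -0.21 for MuLV, -0.06 for young LINE-1, 0.01 for B1, -0.06 for B2, -0.11 for MaLR MT and -0.10 for the list of GLN and RLTR1 elements, whose name pattern took in 80 names, RLTR10 to RLTR19 among them. As shares of all repeat fragments, MuLV lay at -0.02, B2 at 0.03 and MaLR MT at 0.04 in log2, so the small folds depend on the scale. The major and minor satellites were listed at 0 in both libraries. Over 969 repeat names with a summed TPM of at least 5, 64 were at least 2-fold higher and 65 lower. The most extreme of these, Tigger6b (11 and 2 fragments) and tRNA-Ala-GCY (0 and 2 fragments), rested on a handful of fragments. With 50 fragments or more over both libraries, a minimum chosen after the values were seen, 17 were higher and 22 lower on the TPM scale. The fold of the highest of these, L1MA9, depended on the scale. It had 276 TPM in TKO and 1514 in TKO_FL (log2 2.45), but 118 and 164 fragments (interval of the fragment ratio 0.30 to 1.00 in log2).

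**Figure D2:**
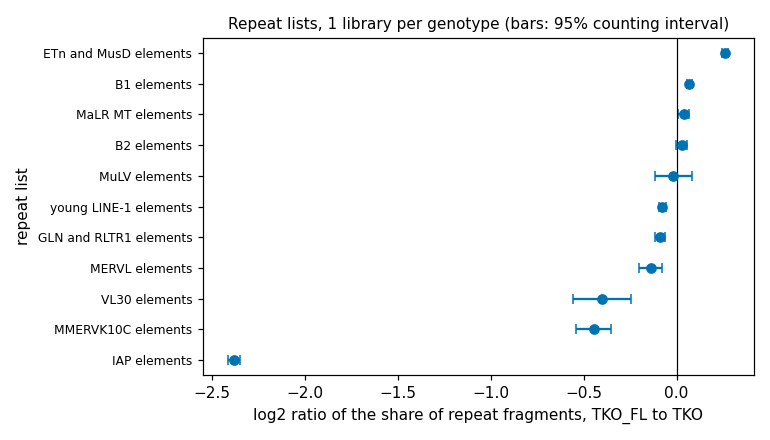
Log2 ratio, TKO_FL to TKO, of the share of all repeat fragments (x axis) for each repeat list with fragments (y axis), from 1 library per genotype; bars are 95% exact binomial intervals for counting error only. IAP elements lie at -2.38, and ETn and MusD elements at 0.26.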

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

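Alternatives with genes under 200 bases left out, TPM computed from the TKO_602 counts, thinned TKO_602 reads, repeat values as shares of all repeat fragments and a minimum of 50 repeat fragments were chosen after seeing the data. The count of genes between TKO_FL and TKO, 906 as reported, was 1621 with a pseudocount of 0.1, 189 with 5, 499 with a TPM of at least 5 and 112 at a 4-fold threshold. Between TKO_602 and TKO, 2614 as reported, it was 1212 with a pseudocount of 5 and 330 at 4-fold, and between TKO_602 and TKO_FL, 1591 as reported, 618 and 101. The other scalings and filters kept these counts within 1.5 times. With TPM computed from the counts, the median of all genes lay at 0.11 in TKO_602 against TKO and the higher genes made up 63.7% of those apart, where the reported share was 57.6%. The numbers of lists outside the central 95%, 11, 14 and 13 of 22 in the 3 comparisons, stayed within 1.5 times under every alternative run for them. Of 414 recomputed list and IAP values, 372 kept their sign and side, 21 came to lie within the central 95% and 8 outside it. Medians that lay within it changed sign or reached 0 in 10 cases, of 2-cell-stage genes (TKO_FL against TKO, -0.36 without predicted symbols, -0.0034 with median-of-ratios factors, 0 with no filter), neuroectoderm (TKO_FL against TKO, -0.065 with no filter and -0.055 with a TPM of at least 5; TKO_602 against TKO, 0.014 with no filter), the Rhox, Mage and Xlr clusters (TKO_FL against TKO, 0 with no filter), mesoderm (TKO_602 against TKO_FL, -0.012 with a pseudocount of 5, 0 with no filter) and DNA methylation genes (TKO_602 against TKO_FL, 0 with no filter). Medians outside it did so in 3: the mesoderm median of TKO_602 against TKO, 0 with no filter, and the neuroectoderm median of TKO_602 against TKO_FL, 0.10 with no filter and 0.076 with a CPM of at least 5; without a filter unexpressed members enter the medians, and for the other the cause was not tested. The summed IAP fold stayed between -2.38 and -2.08. The 129 repeat names apart were 215 with a sum of at least 1, 46 with at least 20 and 250 at 1.5-fold. They were 85 as shares of all repeat fragments and 39 with 50 fragments or more. Without each name's highest feature, which joins copies across chromosomes, they were 76. The strict minimums remove names with few fragments. The correlation of the 2 differences from TKO was 0.605 and 0.592 with pseudocounts of 0.1 and 5 and 0.611 with a CPM of at least 5. With a minimum of 5 in one library too few members were left for a median of mesoderm and Hox genes in the 3 comparisons and of 2-cell-stage genes in those of TKO_602. Rescaling without mitochondrial genes gave no value, since the table has none. No paired analysis was possible because each genotype has 1 library. At this depth the TPM of genes under 200 bases rests on few fragments.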

Other observations

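The values of 3 gene groups defined by symbol or chromosome, which were chosen after their values were seen and have no test, follow. The 4 Id genes, which encode inhibitors of basic helix-loop-helix factors, were all at least 2-fold lower in TKO_602 than in TKO_FL (median -1.75) and 2 of them at least 2-fold lower than in TKO (median -1.09), while their median in TKO_FL against TKO was 0.68. Of 10 expressed interferon-inducible GTPase genes of the Gbp, Irgm, Igtp and Tgtp families, 7 were at least 2-fold lower in TKO_602 than in TKO (median -1.52) and none higher. Of 8 expressed genes on chromosome Y, 2 were at least 2-fold lower in TKO_602 than in TKO, none was higher and 6 lay below 0 (median -0.59). Over the 19 autosomes and X, the chromosome medians of TKO_602 against TKO ranged from -0.08 to 0.07, and those of TKO_FL against TKO from -0.05 to 0.06.

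All tests in the following paragraphs were chosen after the data had been seen; for that of depth, the outcome that would count against the explanation was set before its value was computed. Primitive endoderm genes were lower in TKO_FL than in TKO, together with feeder markers. Fewer feeder fibroblasts alone would lower the endoderm list no more than the feeder list, but its median was further down (difference in log2 -1.49, 95% bootstrap interval over members -2.10 to -0.74), although fibroblasts also express list members such as Col4a1. That interval treats members as independent, although members of a list are often regulated together. The feeder markers were mixed, with 5 of 25 at least 2-fold lower and 2 above 0. Their median is therefore no firm limit on a loss of feeders. A smaller share of primitive-endoderm-like cells may also account for the lower primitive endoderm genes. That stays open. The counting intervals of 12 of the 16 members left out the list median, but this cannot test for a common factor. The intervals have no pseudocount and the median does, so low genes can miss it on that ground alone. Gata6's interval (-4.62 to -3.06) left out even its own fold of -2.95. Expression in other cells would also blur a common factor. The difference in genotype, Dnmt1 included, is open too and untested, and 1 library per genotype cannot separate these.

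TKO_602 differed from TKO in more genes than TKO_FL did. Depth could have inflated the count, but with TKO_602 reads thinned to the TKO total 2672 genes were 2-fold apart. The rank correlation across genes of fold and exonic length was 0.078, so folds showed little steady trend with length. Such a correlation cannot exclude a bias limited to short or long genes, so a length bias of that kind stays open. Reads shared with pseudogene copies named by the gene's own symbol and -ps stay open for 35 of the 2614 genes apart, or 1.34%, Gapdh among them. Of the 318 genes with such a copy, 11.01% were 2-fold apart. That is below the 19.01% of all genes but within the central 95% of random lists matched on expression (9.43% to 17.0%). Copies under other symbols were not searched, so 35 is no upper limit for genes with any copy. A different batch or clone and the genotype itself cannot be told apart, since TKO_602 is 1 library from another folder of alignments.

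IAP transcripts were lower in TKO_FL than in TKO. A scaling of the table would move related families alike, but the summed ETn and MusD fold was 0.21. Whether a few deviating copies account for the difference stays open: 511 of the 516 IAPEz-int features with signal, or 99.03%, were lower, but 515 of the 516 held fractions of fragments in at least 1 library, and sharing would spread the signal of a few copies over many features. The sharing of multi-mapped fragments could not be tested either, because whole values in both libraries were found in 1 feature, with 0 fragments in TKO and 4 in TKO_FL. The difference in genotype, Dnmt1 included, stays open too and was not tested, since each genotype has 1 library.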
